A study of Mus musculus with 2 samples.

How the data were processed

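H3K4me3, a histone modification found at active promoters, was measured by ChIP-seq in the liver of mouse embryos at embryonic day 16.5. The labels give 1 group with 2 samples, called biological replicates 1 and 2. Each was made from livers pooled over male and female embryos of the strain B6NCrl, and the labels give 41 embryos for replicate 2. With no second condition, tissue or age, no comparison between groups was possible.

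The authors deposited 4 peak lists in narrowPeak format on the mm10 build, per the notes deposited with them. Of these, 1 list was called on each replicate's filtered alignments against control alignments, 1 on the pooled replicates, and 1 holds the replicated peaks. The replicated peaks were derived by the authors from the pooled list and both single-replicate lists, and each of them is also a peak of the pooled list. Of 26971 replicated peaks, 26083 (96.7%) overlapped a peak of replicate 1 and 26515 (98.3%) a peak of replicate 2. A replicated peak is thus not always a peak in both single-replicate lists. The aligner, peak caller, thresholds and the rule for a replicated peak are not given in the sources used here. Each peak in the deposited lists carries a signal value, a measure of enrichment that is never negative and whose scale is not stated. It also carries the −log10 of a q-value, as deposited by the authors. These per-peak values are the authors' own. They were used only to describe, rank or filter peaks within a list, and the signal is given as a value or as a percentile within its list.

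The depth of each library is unknown, because the lists hold no read counts, and no value here was scaled by depth. Shares are given with exact Clopper-Pearson 95% confidence intervals, which cover counting error only. Tests that take genes as units describe these 2 libraries. They do not measure the spread between animals, and neighbouring genes can share a peak.

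Genes and transcription start sites (TSS) were taken from the GENCODE vM21 annotation of GRCm38, the assembly called mm10, and every chromosomal peak was checked to lie within its chromosome in that assembly. It gave 55413 genes on chromosomes, 21938 of them protein-coding, and 132721 start positions. A gene was called marked when a replicated peak overlapped, by at least 1 bp, the 1000 bp on either side of any of its annotated start positions. A domain was made by joining replicated peaks over gaps of at most 1000 bp, and a gene's domain was the widest that overlapped its start windows. The widest 5% of domains among marked protein-coding genes were called broad. Domain widths given as mean ± SD were measured in the 2 replicates' own peak lists, with n = 2. Promoters were classed by the 1000 bp centred on the gene's 5' end as CpG-rich (observed/expected CpG of at least 0.6 and GC fraction of at least 0.5), CpG-poor (observed/expected under 0.4) or intermediate. Replicated peaks were assigned to the start window of a protein-coding gene, else of another gene, else to an exon, an intron or intergenic sequence.

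The design, the tests, 22 gene lists and a set of alternatives were fixed before the data were examined. The lists cover hepatocyte plasma proteins, hepatocyte transcription factors, postnatal liver metabolism, erythroid genes, haematopoietic progenitors, myeloid cells and macrophages, megakaryocytes, lymphoid cells, endothelium, stellate, mesothelial and fibroblast cells, cholangiocytes, neural structural genes, muscle structural genes, structural genes of other endoderm, developmental regulators of other lineages, Hox genes, ribosomal proteins, the cell cycle, imprinted genes, sex chromosome genes, interferon and inflammation genes, and olfactory receptors. Of 648 list symbols looked up, 647 matched the annotation, and non-coding members stayed out of the tests. Each list was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. This was done for the share of marked genes and for the share of broad domains among marked genes. The share marked was tested again within promoters that were not CpG-rich, for lists with at least 5 such members. A list's median domain width was placed as a percentile among 10000 random lists of marked genes of the same size, matched on decile of the gene's highest signal value. Lists with fewer than 5 marked members were left out of that step.

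The genes named were set by rule. These were Alb, Afp, Hnf4a, Cebpa, Cyp7a1, Gata1, Klf1, Hbb-bt, Hba-a1, Alas2, Kit, Runx1, Csf1r, Pf4, Cd19, Stab2, Des, Sox9, Snap25, Myh6, Pax6 and Xist, whatever their values. They were joined by the 10 protein-coding genes with the broadest domains, the genes of the 5 replicated peaks with the highest signal, and, per list, up to 4 marked members with the broadest domains and up to 4 unmarked members in alphabetical order. Genes that share a domain were named together, and any other gene is said to have been chosen after its values were seen.

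Alternatives covered the peak threshold (−log10 q of at least 10), the overlap that counts as shared, the peak list, each replicate left out, the window around start sites, the start sites used, the gap joined, the cut for broad domains, the CpG classes, the background genes and the matching on signal. Further alternatives were added after seeing the data. For these, each 1000 bp promoter was sampled as 32-mers every 25 bp, and a promoter was called duplicated when at least 50% of them occurred elsewhere in the genome, over 65 sequence records searched on both strands. Python 3.11.15 was used with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

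The steps were tested on simulated data. Simulated genes lay far apart, each with 1 start site and at most 1 peak. Joined peaks, shared domains and several start sites per gene were therefore not tested. Peaks simulated as shared were slightly shifted copies of replicated peaks. The state of all 11397 simulated genes was recovered, as were the widths of all 6875 genes simulated as marked and all 13413 peaks simulated as shared. Lists simulated as enriched or broad were called, 0 of 40 lists with no effect were called in the test of marked genes, and 1 of the 40 lay outside the 2.5th to 97.5th percentile for breadth. Replicated peaks on unplaced scaffolds and peaks found only in the pooled list were left out of the gene analyses.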

Results

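H3K4me3, which marks active promoters, was profiled by ChIP-seq in pooled liver of mouse embryos at embryonic day 16.5, a stage at which the liver is both a developing metabolic organ and a main site of blood formation. There was 1 group with 2 biological replicates. The data therefore describe which promoters carried the mark in this tissue, how far it spread, and how well the replicates matched. The list of replicate 1 held 31151 peaks covering 34.97 Mb and that of replicate 2 held 31315 peaks covering 36.3 Mb. The authors' list of replicated peaks held 26971 peaks covering 34.9 Mb, with a median width of 968 bp. Read depth was unknown, and all coordinates are on mm10.

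The replicates marked nearly the same promoters, with similar widths. Of 21938 protein-coding genes, 14271 were marked in both replicates and 7252 in neither. Across genes marked in both, the Spearman correlation of domain width was 0.955, and 94.1% of the widths lay within 1.5-fold of each other. Genes are not independent replicates, so these values carry no p. At the level of peaks, 27511 of the 31151 peaks of replicate 1 overlapped a peak of replicate 2 (88.3%, 95% CI 88.0 to 88.7). In the other direction, 26452 of 31315 did so (84.5%, 95% CI 84.1 to 84.9). The Jaccard index of covered bases was 0.828. Across 21079 peaks matched 1 to 1, the Spearman correlation was 0.964 for the signal value and 0.965 for width, and none of these peaks had an identical signal and width in both lists (0 of them). Peaks that were not shared were narrow and weak, with a median width of 221 bp and a median signal percentile of 13.9 in replicate 1, and 242 bp and 14.3 in replicate 2.

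**Figure D1:**
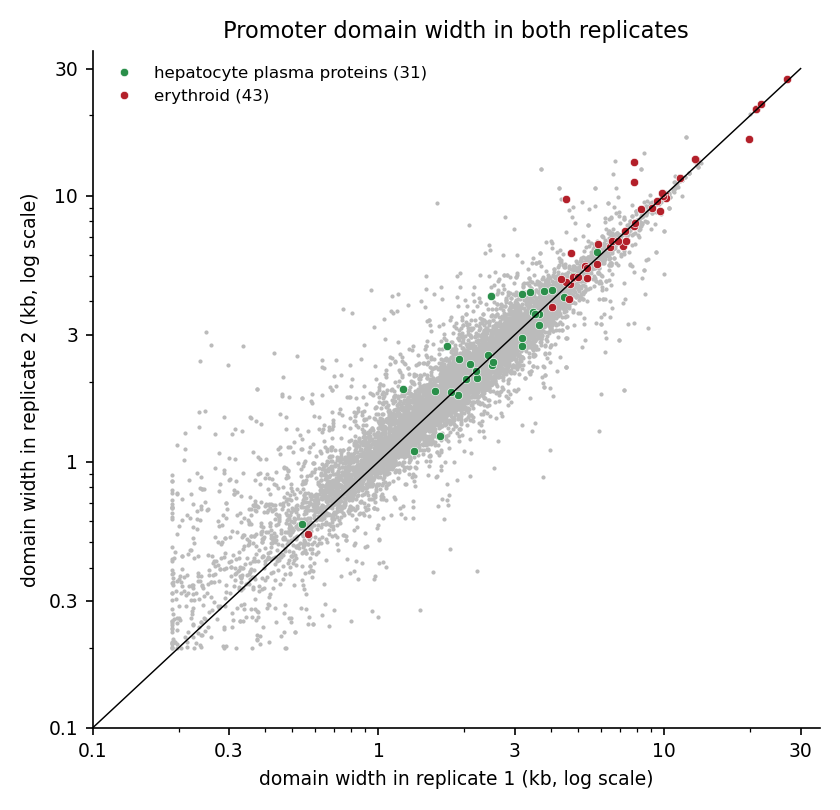
Width of each gene's promoter domain in replicate 1 (x axis, kb, log scale) and replicate 2 (y axis, kb, log scale), with 1 point per protein-coding gene marked in both, 43 erythroid genes in red and 31 hepatocyte plasma protein genes in green. Most points lie near the line of equal width (Spearman correlation 0.955), and most erythroid genes lie toward the upper end.

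The mark lay mainly at promoters. Of 26963 replicated peaks on chromosomes, 16260 overlapped a start window of a protein-coding gene (60.3%, 95% CI 59.7 to 60.9), and these held 80.6% of the covered bases. A further 1336 peaks lay at start sites of other genes (4.95%), 1435 in exons (5.32%), 4635 in introns (17.2%) and 3297 between genes (12.2%). The median signal was 29.7 at protein-coding start sites and 4.34 in introns. The highest signal values were at the promoters of widely expressed genes. Eif4g2, a translation initiation factor, reached 94.4 (chr7:111080127-111083100), Eloa, which encodes elongin A, 93.8 (chr4:136020332-136022242), and Wtap, a subunit of the RNA adenosine methylation complex, 92.6 (chr17:12990387-12993304). Rock1, a kinase acting on the cytoskeleton, and Tm9sf2 each reached 91.3.

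In all, 14319 protein-coding genes were marked (65.3%, 95% CI 64.6 to 65.9), and this share followed the CpG content of the promoter. The share was 97.3% for CpG-rich promoters (9478 of 9740, 95% CI 96.97 to 97.6), 78.5% for intermediate ones (2683 of 3416, 95% CI 77.1 to 79.9) and 24.6% for CpG-poor ones (2158 of 8782, 95% CI 23.7 to 25.5). Gene lists were therefore also compared within promoters that were not CpG-rich, of which about 39.7% were marked.

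Genes of red blood cell formation carried the mark at almost every member. Of 47 erythroid genes, 43 were marked (91.5%, 95% CI 79.6 to 97.6), against 65.2% of other genes (Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 0.000166). Gata1, the master transcription factor of the lineage, lay under a domain of 7896 bp (chrX:7963907-7971802), which measured 7901 ± 2.12 bp over the replicates (mean ± SD, n = 2). Klf1, an activator of the adult beta-globin genes, had a peak at signal percentile 96.8 and a domain of 4631 ± 163 bp (mean ± SD, n = 2). Alas2, the first enzyme of heme synthesis in red cells, had a domain of 7321 ± 50.2 bp, and the adult beta-globin gene Hbb-bt a domain of 6676 ± 132 bp (mean ± SD, n = 2). The 4 unmarked members were the embryonic globin genes Hba-x, Hbb-bh1 and Hbb-y, and Slc25a37, a mitochondrial iron importer, for which 100% of the 32-mers sampled from its promoter occurred elsewhere in the genome.

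Stem and progenitor cell regulators were marked at 26 of 30 genes (86.7%, Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 0.0244). Runx1, a transcription factor needed for the emergence of blood stem cells, had a domain of 7345 ± 153 bp and Kit, the receptor for stem cell factor, 4243 ± 91.9 bp (mean ± SD, n = 2). The broadest members besides Runx1 were Lyl1 (7573 bp), Ikzf1 (7468 bp) and Meis1 (6993 bp), all transcription factors of blood progenitors. Hoxa10, Hoxa9, Mpl and Slamf1 were unmarked. This call was lost when only peaks with a −log10 q of at least 10 were used (80%, exact test, adjusted p = 0.0507) and when receptor genes were left out of the background (adjusted p = 0.0818).

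Lymphoid genes were marked less often than other genes, at 12 of 30 (40%, Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 0.0135). Among the marked were the transcription factor genes Gata3 (7784 bp), Ebf1 (3768 bp) and Pax5 (2106 bp) and the kinase gene Lck (2278 bp), while Blk, Blnk, Cd19 and Cd3e were unmarked. The lymphoid call was lost in replicate 2 alone, with replicate 1 left out (50%, exact test, adjusted p = 0.145), and among promoters that were not CpG-rich (7 of 25, adjusted p = 0.460). Myeloid and macrophage genes were marked at 17 of 30 (56.7%) and megakaryocyte genes at 12 of 20 (60%), neither of which passed the test (exact test, adjusted p = 0.416 and 0.642), but with peaks of a −log10 q of at least 10 the myeloid list was marked less often than other genes (23.3%, exact test, adjusted p = 0.000117). Csf1r, the macrophage growth factor receptor, had a domain of 2326 ± 20.5 bp (mean ± SD, n = 2), and the broadest myeloid domains were at Irf8 (3898 bp), Mafb (3871 bp), Cebpe (3703 bp) and Prtn3 (3084 bp). Aif1, Cd163, Cd5l and Cd68 were unmarked. Of the platelet genes, Nbeal2 (6727 bp), Thbs1 (3096 bp), Itgb3 (2523 bp) and Gp5 (2044 bp) were marked, and F2rl2, Gp6, P2ry12 and Pf4, which had a peak in replicate 1 alone, were not. Clec1b had a peak in each replicate (208 ± 8.49 bp, mean ± SD, n = 2) but no replicated peak.

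Plasma protein genes were marked at 32 of 34 (94.1%, 95% CI 80.3 to 99.3, adjusted p = 0.000568) and hepatocyte transcription factors at 22 of 24 (91.7%, 95% CI 73.0 to 99.0, adjusted p = 0.0115), by Fisher's exact test with Benjamini-Hochberg adjustment. Among the plasma proteins the broadest domains were at Fgg, a fibrinogen chain (5974 ± 198 bp), Vtn, which encodes vitronectin (4893 ± 112 bp), Itih2 (4691 ± 72.1 bp) and the transferrin gene Trf (4089 ± 407 bp; mean ± SD, n = 2 for each). Apoc3 and F9, which encodes a clotting factor, were unmarked. Hnf4a, a central regulator of the hepatocyte network, had a domain of 3265 ± 13.4 bp and Cebpa, another of its regulators, 5274 ± 300.5 bp (mean ± SD, n = 2). The broadest domains of this list were at Prox1 (8104 ± 7.07 bp), Nr2f2 (6590 ± 1608 bp), Klf15 (6786 ± 106 bp) and Onecut2 (6283 ± 654 bp; mean ± SD, n = 2 for each), and the nuclear receptor genes Nr0b2 and Nr1i3 were unmarked. The transcription factor call was lost when only the gene's own 5' end was used (83.3%, exact test, adjusted p = 0.0748) and when receptor genes were left out of the background (adjusted p = 0.0544).

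Alb and Afp, which encode the main plasma proteins of the fetus, were weakly marked in the replicated list. Alb had 1 replicated peak of 275 bp (chr5:90462711-90462985), 1814 bp inside the gene from its 5' end, with a signal of 3.57. Nearer the 5' end, at chr5:90461493-90461733 and chr5:90461795-90462156, replicate 1 had peaks with signals of 4.41 and 5.42, the pooled list had overlapping peaks with a signal of 3.41, and the replicated list had none. Over the replicated peak, replicate 1 had a peak with a signal of 5.76, at percentile 42.5 of its list, and its domain at Alb was 1504 bp. Replicate 2 had no promoter peak at Alb. Afp had a domain of 1448 ± 283 bp (mean ± SD, n = 2; chr5:90491350-90492699) with a signal of 3.87. The signals of 3.57 and 3.87 were the lowest in the replicated list among the 32 marked plasma protein genes, whose median was 9.15.

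Enzymes and transporters that rise after birth were marked at 18 of 34 genes (52.9%, Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 0.235). Using only peaks with a −log10 q of at least 10, they were marked less often than other genes (35.3%, exact test, adjusted p = 0.00475). Aldob (3833 bp) and Ass1 (2648 bp), of fructose metabolism and the urea cycle, were marked, as were Glul (3343 bp) and Arg1 (2418 bp). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was unmarked in both replicates, as were Baat, Cyp1a2, Cyp2e1 and Cyp2f2.

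Genes of the other cell types of the liver were marked to differing extents. The libraries were made from pooled livers, so the cells that carried a mark were not told apart. Endothelial genes were marked at 24 of 30 (80%, adjusted p = 0.208), and within promoters that were not CpG-rich at 18 of 24 (75% against 39.6% of other genes, adjusted p = 0.00170), by Fisher's exact test with Benjamini-Hochberg adjustment. Over all promoters the endothelial list also passed in replicate 1 alone, with replicate 2 left out (86.7%, exact test, adjusted p = 0.0229). Erg (4629 bp), Ltbp4 (4414 bp), Egfl7 (3587 bp) and Gata4 (3044 bp) had its broadest domains. Stab2, a scavenger receptor of sinusoidal endothelium, had a replicated peak of 205 bp and no peak in replicate 1. Clec4g, Dnase1l3, Emcn and Lyve1 were unmarked, although Emcn had a peak in each replicate and Lyve1 in replicate 2 alone. Stellate, mesothelial and fibroblast genes were marked at 17 of 30 (56.7%, exact test, adjusted p = 0.416) and cholangiocyte genes at 15 of 20 (75%, adjusted p = 0.531). The stellate, mesothelial and fibroblast list passed as marked less often when peaks had a −log10 q of at least 10 (40%, exact test, adjusted p = 0.0370). Of the former, Hand2 (4468 bp), Pdgfra (4360 bp), Foxf1 (4252 bp) and Reln (3840 bp) were broadest. Des, an intermediate filament gene of stellate and muscle cells, had 725 ± 101 bp (mean ± SD, n = 2). Unmarked were Dcn and, with a peak in replicate 2 alone, Acta2, Col3a1 and Colec11. Of the latter, Aqp1 (7063 bp), Hnf1b (4476 bp), Sox4 (3949 bp) and Sox9, a regulator of bile duct formation (3439 ± 1195 bp, mean ± SD, n = 2), were broadest, and the keratin genes Krt19 and Krt7, with Cldn4 and Ehf, were unmarked. Within promoters that were not CpG-rich, cholangiocyte genes passed the test only in replicate 2 alone, with replicate 1 left out (78.6%, exact test, adjusted p = 0.0124, against 64.3% and 0.185).

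Muscle structural genes were marked at 7 of 30 (23.3%, adjusted p = 2.6e-05), structural genes of lung, pancreas, stomach and intestine at 2 of 30 (6.67%, adjusted p = 2.8e-10), and olfactory receptor genes at 3 of 1093 (0.274%, 95% CI 0.0566 to 0.800), by Fisher's exact test with Benjamini-Hochberg adjustment. Of the muscle genes, Tnnc1 (4529 bp), Myl4 (2696 bp), Myl3 (2278 bp) and Ckm (1083 bp) were marked, each on a domain shared with another protein-coding gene, while Myh6, Acta1, Actc1, Casq1 and Casq2 were not. Cela1 (2626 bp) and Tff3 (387 bp) were the 2 marked endoderm genes, and Amy2a5, Cela2a, Clca1 and Cpa1 were unmarked. The 3 marked receptor genes were Olfr1033, Olfr56 and Olfr94, named after their values were seen. Within promoters that were not CpG-rich the muscle call held (4 of 27, 14.8%, exact test, adjusted p = 0.0192), but not with a window of 2.5 kb (22.2%, adjusted p = 0.106) or with the pooled list (18.5%, adjusted p = 0.0602).

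Neural structural genes were marked at 15 of 30 (50%), developmental regulators of other lineages at 23 of 40 (57.5%) and Hox genes at 24 of 39 (61.5%), and none of these lists passed Fisher's exact test after Benjamini-Hochberg adjustment (adjusted p = 0.158, 0.416 and 0.642). Snca, highly expressed in red cells as well as neurons, had the broadest neural domain (5437 bp), followed by Gfap (3793 bp), Mbp (2438 bp) and Mapt (1933 bp), while Snap25, a synaptic gene, and Aqp4, Camk2a, Cplx1 and Dcx were unmarked. Pax6, an eye and brain regulator, had a domain of 2834 ± 36.8 bp (mean ± SD, n = 2), with Six1 (2774 bp), Atoh1 (2243 bp) and Nkx6-1 (2161 bp) next, and Lhx3, Lhx5 and the muscle regulators Myf5 and Myod1 were unmarked. Hoxb4 (2414 bp), Hoxb2 (1814 bp), Hoxa5 (1710 bp) and Hoxa4 (1681 bp) were the broadest Hox genes, and Hoxa10, Hoxa11, Hoxa9 and Hoxb1 were unmarked. With peaks of a −log10 q of at least 10, all 3 lists were marked less often than other genes (33.3%, 37.5% and 35.9%, exact test, adjusted p = 0.00475, 0.00524 and 0.00359), as was the neural list with a window of 500 bp (43.3%, adjusted p = 0.0371). Within promoters that were not CpG-rich, the developmental list was marked more often than other genes in replicate 2 alone, with replicate 1 left out (80%, exact test, adjusted p = 0.0356).

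All 54 ribosomal protein genes (adjusted p = 8.2e-10) and all 30 cell cycle genes (adjusted p = 1.8e-05) were marked, by Fisher's exact test with Benjamini-Hochberg adjustment. The broadest ribosomal domains were at Rpl35 (6569 bp), Rps18 (6378 bp), Rps2 (6009 bp) and Rpl18 (5469 bp), each shared with other genes. The broadest cell cycle domains were at E2f2 (10605 bp), Pcna (7858 bp), Rrm2 (7036 bp) and the proliferation marker Mki67 (5252 bp).

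Imprinted genes were marked at 22 of 24 (91.7%, Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 0.0115), led by Gnas with Nespas (7716 bp), Igf2 (6694 bp), the fetal growth factor, and Zrsr1 (6149 bp), and Ndn and Rtl1 were unmarked. This call was lost with peaks of a −log10 q of at least 10 (79.2%, exact test, adjusted p = 0.113), with only the gene's own 5' end (75%, adjusted p = 0.317) and with receptor genes left out of the background (adjusted p = 0.0544). Interferon and inflammation genes were marked at 13 of 25 (52.0%, Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 0.302). Nfkbia (3932 bp), Irf9 (3215 bp), Socs3 (3192 bp) and Stat2 (3169 bp) were broadest, and Ccl2, Ccl5, Hamp and Ifit3 were unmarked. In these pools of both sexes, Xist, the RNA that silences an X chromosome in females, had a domain of 4129 ± 96.2 bp (mean ± SD, n = 2). The Y-linked list was marked at 4 of 8 protein-coding genes (exact test, adjusted p = 0.531), among them Ddx3y (1885 bp), Eif2s3y (1521 bp) and Uty (1164 bp), while Sry, Usp9y, Zfy1 and Zfy2 were unmarked.

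Over all promoters, 7 of 22 lists were marked more often than other genes, 4 less often, and 11 did not pass. Within promoters that were not CpG-rich, plasma proteins (30 of 32, adjusted p = 1.7e-09), erythroid genes (31 of 34, adjusted p = 3.4e-09), hepatocyte transcription factors (12 of 14, adjusted p = 0.00170), imprinted genes (12 of 14, adjusted p = 0.00170), progenitor genes (14 of 18, adjusted p = 0.00333) and ribosomal proteins (6 of 6, adjusted p = 0.00910) were again marked more often by Fisher's exact test with Benjamini-Hochberg adjustment, as were the endothelial genes. Olfactory receptors (3 of 1093, adjusted p = 1.7e-246) and the other endoderm list (2 of 30, adjusted p = 0.000498) were again marked less often by the same exact test.

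**Figure D2:**
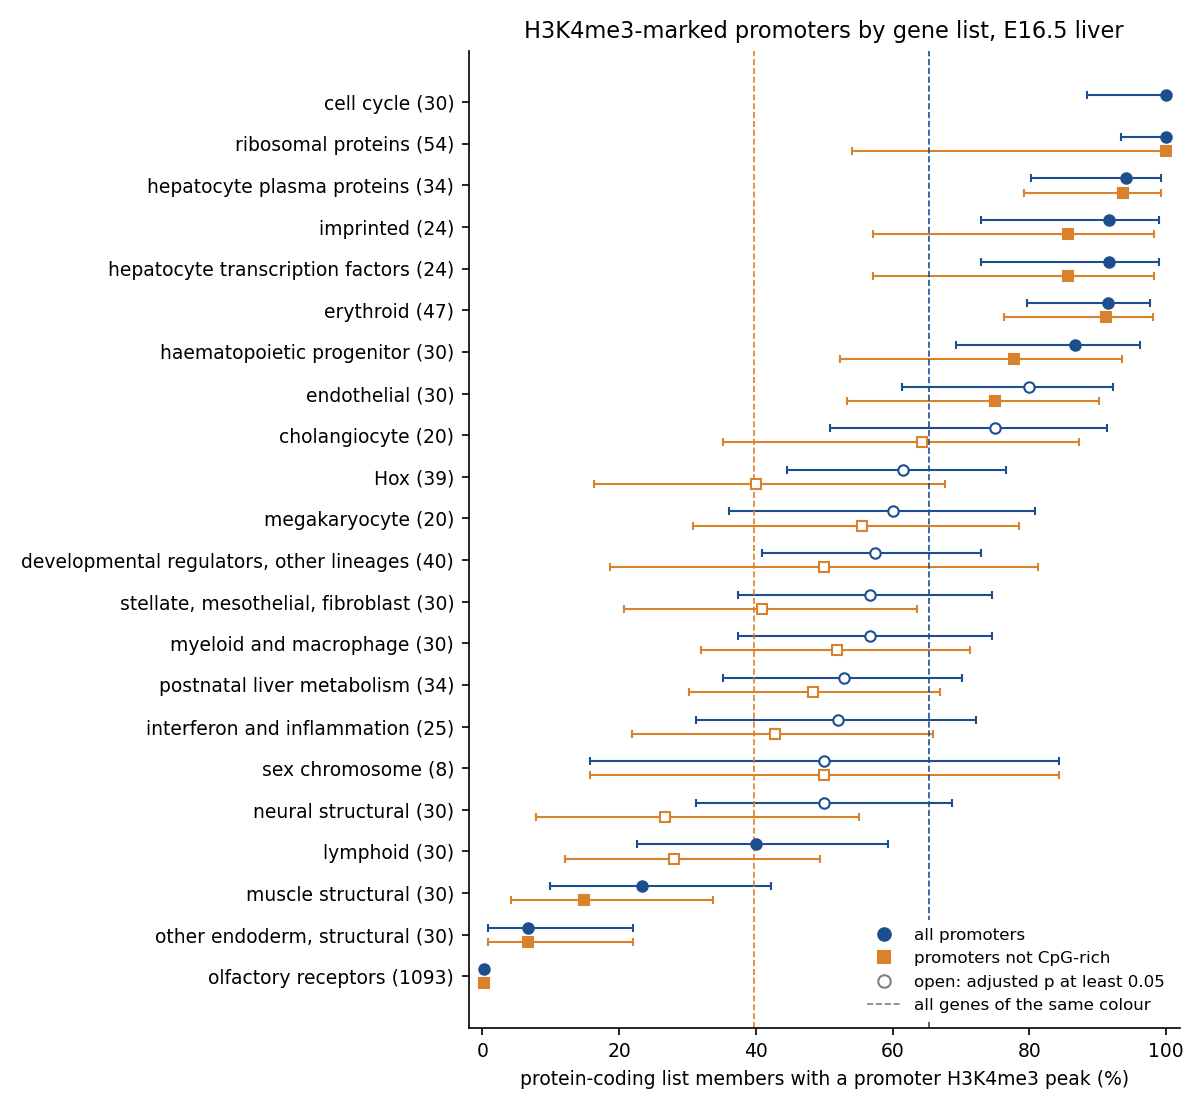
Share of protein-coding members of each gene list with a promoter H3K4me3 peak (x axis, %), with 95% exact confidence intervals, for all promoters (circles) and for promoters that are not CpG-rich (squares). Filled symbols passed the test, dashed lines give the share over all genes (65.3% for all promoters), and the list sizes are in parentheses.

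Erythroid genes had by far the broadest promoter domains of any list. A domain counted as broad at 5113 bp, which took in 718 genes on 546 domains. Of 43 marked erythroid genes, 31 lay on broad domains (72.1%, 95% CI 56.3 to 84.7), against 4.81% of other marked genes (Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 5.2e-30). The list's median width was 7270 bp, against 2168 bp in random lists matched on signal, and it lay at percentile 100 of them. In the replicates it was 7504 ± 229 bp (mean ± SD, n = 2). Plasma protein genes, although 94.1% of them were marked, were broad at 1 of 32 (3.13%, adjusted p = 1 by the same Fisher's exact test), with a median width of 2458 bp. This was also wider than in random lists matched on signal, whose median was 1110.5 bp, and lay at percentile 100 of them.

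Of the other lists, hepatocyte transcription factors were broad at 5 of 22 genes (22.7%, Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 0.0444), a call lost with the pooled peak list (18.2%, adjusted p = 0.122). Progenitor genes (5 of 26, adjusted p = 0.0627), imprinted genes (4 of 22, adjusted p = 0.123) and cell cycle genes (4 of 30, adjusted p = 0.269) did not pass the exact test. These calls changed with the replicate used, as progenitor genes passed the exact test in each replicate alone (29.6% and 19.2%, adjusted p = 0.000262 and 0.0465 with replicate 1 or 2 left out), cell cycle genes with replicate 1 left out (20.0%, adjusted p = 0.0178) and imprinted genes with replicate 2 left out (22.7%, adjusted p = 0.0293). Progenitor and cell cycle genes also passed the exact test with single peaks (30.8% and 20.0%, adjusted p = 0.000292 and 0.0180) and with the broadest 10% (42.3% and 36.7%, adjusted p = 0.000149 and 0.000479). With each domain counted once, progenitor, cell cycle and imprinted genes passed the exact test (19.2%, 20.0% and 23.8%, adjusted p = 0.0373, 0.0179 and 0.0179). Ribosomal proteins were broad at 4 of 54 genes, and each remaining list had at most 1 broad member.

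Matched on signal, 12 of the 19 lists with enough marked members lay above the central 95% of random lists in median width. A gene's width was that of its widest domain over all of its start sites. The random lists were not matched on the number of start sites or on CpG class. Breadth was also not measured with only the gene's 5' end, so an effect of these on the percentiles was not tested. Besides the erythroid list, the lists above the central 95% included hepatocyte transcription factors (median 3974 bp), cell cycle genes (3694 bp), progenitor genes (3631 bp), ribosomal proteins (2994 bp), plasma proteins (2458 bp), imprinted genes (2440 bp), stellate, mesothelial and fibroblast genes (1993 bp), myeloid genes (1823 bp), postnatal liver genes (1813 bp), cholangiocyte genes (1808 bp) and endothelial genes (1551 bp). Lymphoid (1709 bp), interferon (1961 bp), developmental (1073 bp), neural (1077 bp), muscle (1083 bp) and megakaryocyte genes (1035 bp) lay within it. Hox genes had the narrowest domains, at 662 bp and percentile 2.12, but percentile 36.3 in replicate 1 alone, with replicate 2 left out, 3.64 with single peaks and 90.8 with gaps of up to 3 kb joined. When random lists were not matched on signal, 5 lists lay above and 6 below, and the endothelial list turned from percentile 99.9 to 1.82.

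**Figure D3:**
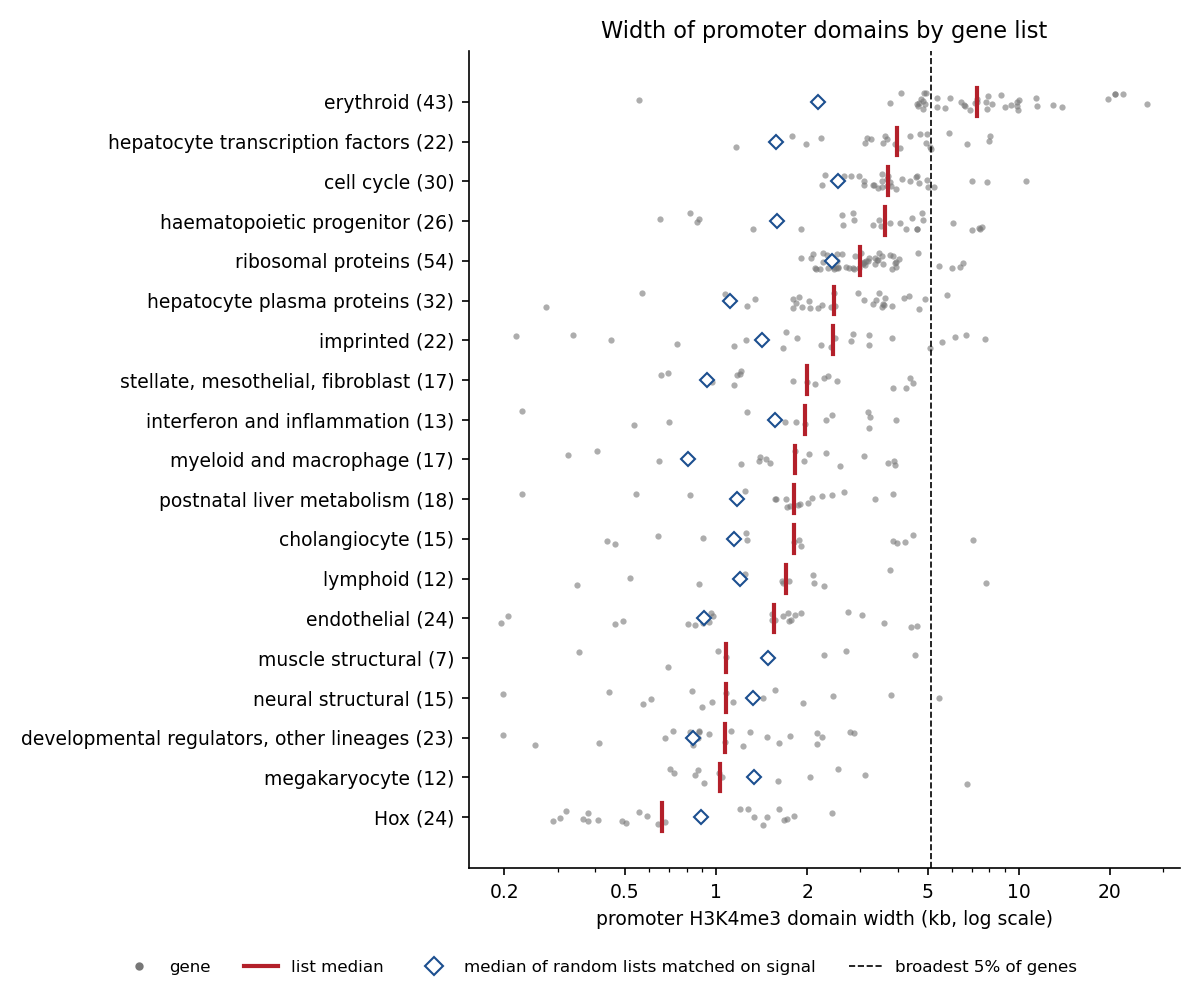
Width of the promoter H3K4me3 domain (x axis, kb, log scale) of each marked gene, by gene list with the number of marked genes in parentheses. Red bars are list medians, diamonds are medians of random lists matched on signal and the dashed line is the limit of the broadest 5% of genes; the erythroid median of 7270 bp is the only one beyond it.

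The widest domain, 26617 bp at chr8:23033361-23059977, lay inside Ank1, which encodes a protein of the red cell membrane skeleton, and 97.9% of it was intronic. It measured 27215 ± 322 bp in the replicates (mean ± SD, n = 2). The next, of 22025 bp at chr15:103237401-103259425, held Nfe2, an erythroid and megakaryocyte transcription factor, together with Cbx5 and Hnrnpa1 (21908 ± 171 bp, mean ± SD, n = 2). The adult alpha-globin genes Hba-a1 and Hba-a2, with Hbq1a and Hbq1b, shared a domain of 20725 bp at chr11:32281195-32301919 (21063 ± 88.4 bp, mean ± SD, n = 2). It was made of 15 peaks, and the gaps between them covered 89.9% of Hba-a1 and 84.7% of Hba-a2. A domain of 19842 bp at chr2:173019426-173039267 held Rbm38 (20058 ± 236 bp, mean ± SD, n = 2). A domain of 19778 bp at chr4:132059891-132079668 held Epb41, another membrane skeleton gene, with Gm10300 (18050 ± 2396 bp, mean ± SD, n = 2).

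**Figure D4:**
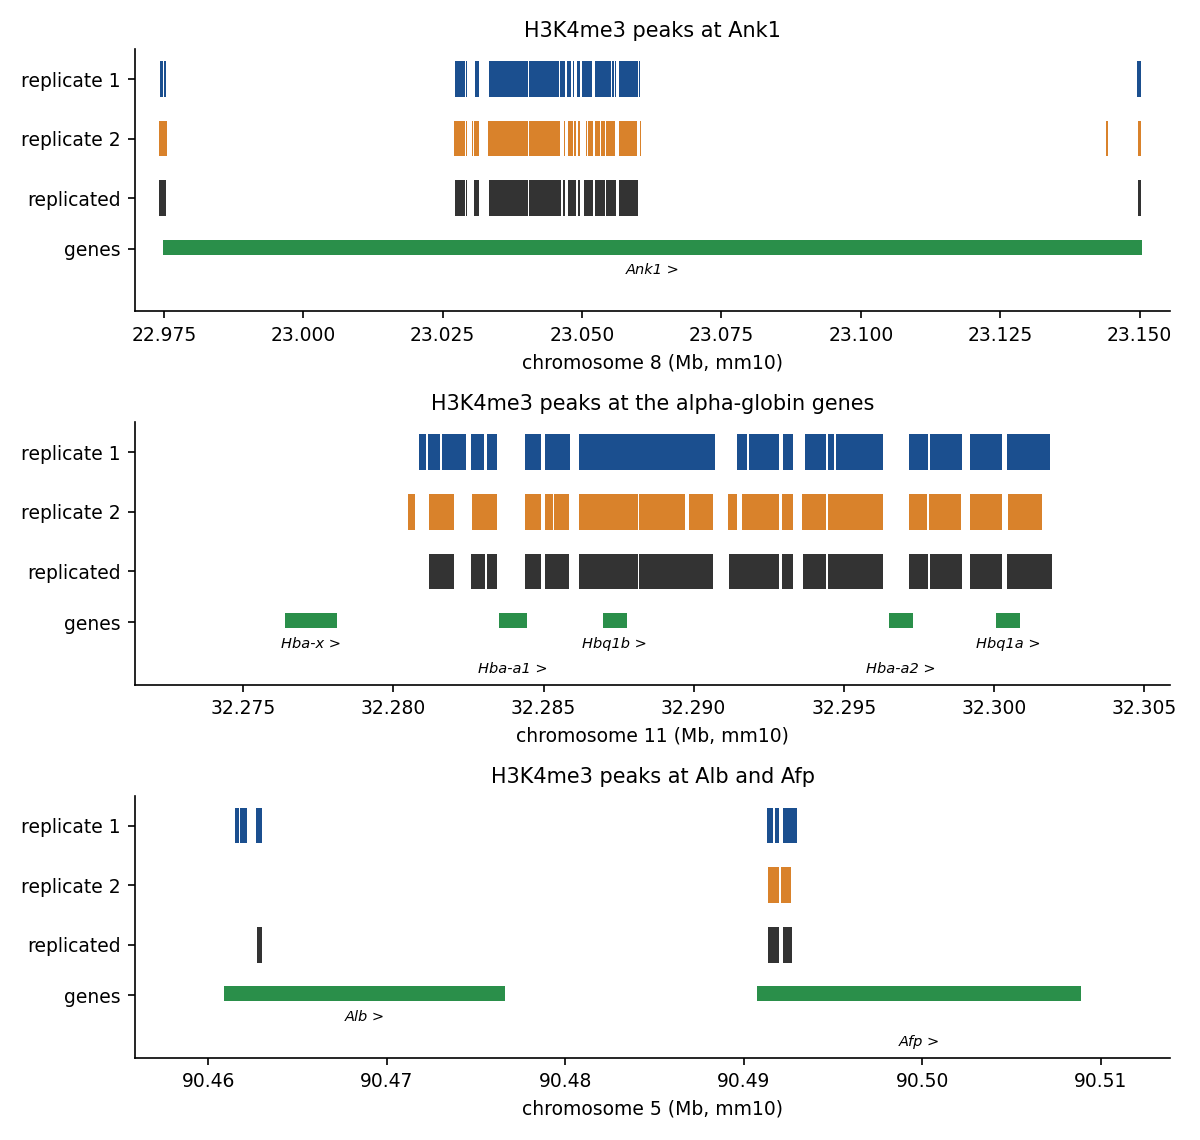
Peaks of replicate 1, replicate 2 and the replicated list at Ank1, the alpha-globin genes, and Alb and Afp (x axes, position in Mb on mm10), with genes as green bars and arrows for their direction. Peaks lie close together across the domains of 26617 bp in Ank1 and 20725 bp at the alpha-globin genes, with gaps over most of Hba-a1 and Hba-a2, and Alb has 1 replicated peak of 275 bp.

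Few genes were marked in a single replicate. There were 106 in replicate 1 (0.737% of its marked genes) and 309 in replicate 2 (2.12%), with median signal percentiles of 18.0 and 20.4 within their lists. Of these, 79 and 253 had no peak of the other replicate within 5 kb of a start site. A replicated peak still marked 17 of the 106 and 82 of the 309. On the fixed lists were 12 genes of replicate 1, among them Alb, Nr0b2 and Pf4, and 29 genes of replicate 2, among them Cd19, Stab2 and Hoxa9. Other genes named above as unmarked also had a peak in replicate 2 alone. These were Acta2, Casq2, Cd68, Col3a1, Colec11, Cplx1, Ehf, Hoxa11, Krt19, Lhx3 and Lyve1. Cd19, part of the B cell co-receptor, had a peak of 243 bp at signal percentile 18.2 in replicate 2. Gata1, Csf1r and Pax6 were marked in both replicates, but away from the gene's outermost 5' end.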

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

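The tests of joined promoters and of peak height below were chosen after the result was seen, while the other tests were set out before their values were seen. With 1 group, no biological explanation was tested for any pattern.

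Signal in data that the comparisons do not use came from the pooled peak list, which held 1520 peaks that overlap no replicated peak. They were narrow, with a median width of 217.5 bp and a median signal percentile of 6.57, and 379 lay at a protein-coding start site. They would add 74 marked genes, among them Casq2, Colec11, Cplx1 and Gap43, the last of these named after its values were seen. The replicated list also held 8 peaks on 5 unplaced scaffolds, covering 7429 bp with a signal of up to 67.2, which entered no gene analysis.

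The first pattern weighed was the broad domains at erythroid genes. Joining of neighbouring promoters is excluded as the whole cause, since 66.67% of erythroid genes alone on their domain were broad, against 3.48% of other such genes (Fisher's exact test, p = 2.0e-24). Height of the peaks, taken as the decile of a gene's highest signal, is excluded as the whole cause of the median width. That median was 7270 bp, against 2168 bp in random lists matched on signal, and lay at percentile 100 of them. Genes were drawn singly for these lists, so shared domains were not matched. The share of broad domains was not tested in this way. Plasma protein genes, broad at 1 of 32, also lay at percentile 100, so this percentile alone does not set erythroid genes apart. Reads shared between copies of promoters are excluded as the whole cause. Of erythroid genes with promoters that were not duplicated, 70.73% were broad (29 of 41, from 31 of 43 in all), against 4.73% of others (Fisher's exact test, p = 3.1e-29). Only the 1000 bp at the gene's 5' end were examined, so repeated sequence elsewhere in the domains was not tested. The cause of the pattern stays open, since transcription of these genes was not measured here, and transcript levels and the share of erythroid cells in the same samples would be needed to weigh it.

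The second pattern was the 262 CpG-rich promoters without the mark, in a class of which 97.3% were marked. Duplicated sequence is consistent with part of it, since 26.72% of them were duplicated (95% CI 21.5 to 32.5) against 0.591% of marked CpG-rich promoters (Fisher's exact test, p = 5.489e-79), but this share excludes duplication as the whole cause. Peaks just outside the start windows are excluded as the main cause, since 9.924% of these genes had a replicated peak within 5 kb. Of the 262 genes, 61 had a promoter peak in the list of at least 1 replicate, and 22 were on the developmental, Hox or neural lists. For 170 of the 262 neither explanation applied, 52 of which had such a peak, and what sets the 170 apart stays open.

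The third pattern was the gaps between peaks inside the alpha-globin domain, which take 4448 of its 20725 bp. Sequence shared by the gene copies may account for part of them. Of the 32-mers in all of these gaps, 67.29% occurred elsewhere in the genome, against 22.7% of those in the peaks. Repeated sequence was not always left as a gap, since 3593 repeated 32-mers lay in the peaks and 2701 in the gaps. The gaps covered 89.9% of Hba-a1 and 84.7% of Hba-a2, but 21.99% of Hbq1a and none of Hbq1b. Whether repeated sequence differs between these genes in the same way was not tested. How the authors treated reads that align to several places is not given in the sources used here. The weak marks at Alb and Afp had been looked at first in its place, where 0% and 12.8% of promoter 32-mers were repeated and no replicated peak within 5 kb had a signal above 3.87.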

How the results depend on the processing

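Of the alternatives below, those on erythroid subsets, on CpG-rich promoters, on duplicated promoters and on breadth without a replicate were added after seeing the data. Depth is unknown, so its effect on weak peaks was not measured. No paired analysis was possible because there is 1 group. Over 145 results, 794 alternative values were computed. Of these, 664 were counted as unchanged and 130 were not, and 1 of the 130 reversed. Unchanged meant the same call for a list or gene, a value within its spread or, for a count, within 1.5-fold of the main value. Where a value changed, the cause was not tested.

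The erythroid share in broad domains was 66.67% to 93.0% under every alternative run, and passed in each.

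With peaks of a −log10 q of at least 10, 17069 (96.11%) and 16904 (92.03%) peaks of replicates 1 and 2 were shared, and 755 replicated peaks lay at other start sites, 592 in exons, 1426 in introns and 1505 between genes. Then 10 lists were marked less often than other genes, newly postnatal liver (35.29%), myeloid (23.33%), stellate (40%), neural (33.33%), developmental (37.5%) and Hox genes (35.9%), and the progenitor (80%) and imprinted (79.17%) calls were lost. Requiring 50% of both peaks, 73.18% and 72.8% were shared, with rank correlations of 0.9714 for signal and 0.9739 for width, and requiring it of the smaller peak 85.68% and 82.08%.

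With a window of 2.5 kb, 838 peaks lay in exons and 3003 in introns, and muscle genes that were not CpG-rich (22.22%) no longer passed, nor with the pooled list (18.52%). With 500 bp, neural genes passed as lower (43.33%). With CpG limits of 0.75 and 0.48, 98.9%, 91.11% and 29.13% of rich, intermediate and poor promoters were marked, and with a window of 2 kb 98.29%, 90.35% and 26.99%. Without receptor genes in the background, 4 lists were higher, and the calls of transcription factors (91.67%), progenitor (86.67%) and imprinted genes (91.67%) were lost. With only the gene's 5' end, transcription factors (83.33%) and imprinted genes (75%) lost theirs.

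In broad domains, 1 list was higher with the pooled list, where transcription factors lost their call (18.18%). There were 4 with single peaks, newly progenitor (30.77%) and cell cycle genes (20.0%), 4 with the broadest 10% (42.31% and 36.67%), and 5 with each domain counted once (19.23%, 20.0% and, for imprinted genes, 23.81%). For breadth, 0 lists lay below the 2.5th percentile with single peaks or gaps of 3 kb joined. Not matched on signal, 5 lists lay above and 6 below, and endothelial genes reversed to percentile 1.815.

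Without either replicate in turn, shares ranged from 40% to 50% for lymphoid, 83.33% to 86.67% for endothelial, and, not CpG-rich, 64.29% to 78.57% for cholangiocyte and 50% to 80% for developmental genes. In broad domains 4 lists were higher without either, with 19.23% to 29.63% of progenitor, 13.33% to 20.0% of cell cycle and 18.18% to 22.73% of imprinted genes, and 0 to 1 lists lay below the 2.5th percentile of breadth.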

Other observations

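The tests here of CpG-rich promoters, histone genes, domains without a protein-coding start site and erythroid against plasma protein genes were chosen after the data were seen. Within CpG-rich promoters, of which 97.3% were marked, the developmental, Hox and neural lists were marked less often than other genes. Developmental regulators were marked at 18 of 30 (60%, adjusted p = 8.2e-11), Hox genes at 18 of 24 (75%, adjusted p = 0.000208) and neural structural genes at 11 of 15 (73.3%, adjusted p = 0.00239), by Fisher's exact test with Benjamini-Hochberg adjustment. The calls were the same with duplicated promoters left out (exact test, adjusted p = 2.3e-12, 3.8e-05 and 0.000767). No member of these lists was removed by this step, which changed only the genes they were compared with. It was therefore no separate check on the lists.

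Erythroid and plasma protein genes, both marked at most members, differed in the width and signal of the mark. Median domain widths were 7270 and 2458 bp, and median signal percentiles 76.5 and 47.3, each with p = 2e-05 in a two-sided permutation test over genes, the smallest value these permutations can give. The width difference was 4858 bp in replicate 1 and 4945 bp in replicate 2. These widths were not matched on signal. Random lists matched on signal to the erythroid and plasma protein genes had medians of 2168 and 1110.5 bp. Whether the 2 lists differ in width beyond signal was therefore not tested. Histone genes, which are transcribed in S phase, also lay on broad domains, at 43 of 60 marked genes (71.7%). These genes lie in clusters and share domains, of which 15 of 27 were broad, and of the 8 histone genes alone on their domain 1 was broad. The breadth of histone domains was thus not told apart from the joining of neighbouring promoters, as in the 13018 bp domain at chr13:22032965-22045982, which holds Hist1h2ag, Hist1h2ah, Hist1h2bj, Hist1h2bk and Hist1h4i (13063 ± 99.0 bp, mean ± SD, n = 2).

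Of 21154 replicated domains, 6873 held no protein-coding start site, and 26 of these were broad. The widest, 10676 bp, lay at the haematopoietic microRNA gene Mir142 (chr11:87748149-87758824) and measured 5929 bp in replicate 1 and 10684 bp in replicate 2. Others lay at the nuclear RNA genes Neat1 (8881 ± 111 bp) and Malat1 (8956 ± 315 bp) and at Lockd (8492 ± 708 bp; mean ± SD, n = 2 for each). The Neat1 domain also overlapped the protein-coding gene Frmd8, and the Lockd domain the protein-coding gene Cdkn1b. A domain of 9036 bp at chr19:12004590-12013625 overlapped no annotated gene and lay 10478 bp from Osbp, its nearest protein-coding gene (9050 ± 112 bp, mean ± SD, n = 2). The erythroid microRNA genes Mir144 and Mir451a shared a domain of 10896 bp with Eral1 (11005 ± 273 bp, mean ± SD, n = 2), and these genes, like the others in this paragraph, were chosen after their values were seen.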
